A study of Mus musculus with 2 samples.

How the data were processed

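ATAC-seq, which cuts open chromatin with a tagging transposase and sequences the fragments, was run on midbrain dissected from mouse embryos of the B6NCrl strain at embryonic day 11.5. The labels give 1 group with 2 biological replicates of pooled male and female embryos, 109 embryos in replicate 1 and 88 in replicate 2. Chromatin was tagmented with Nextera enzyme, per the labels. There was no second tissue, age or treatment, so every comparison was made between the replicates, between deposited lists, or with the genome and with matched random sets.

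The deposited files used were peak lists on the mm10 assembly. Per the README inventories deposited with the samples, each replicate had its own lists from its own alignments, and further lists were made from the alignments of both replicates together, here called pooled. The aligner, the peak caller, their versions, the read filters and any shift of read ends for the transposase were not given in the sources used here. A shift of a few bases would move summits by less than any window used below. Each list row held a peak interval and its summit, and overlapping rows could carry several summits of 1 accessible region.

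The enrichment of a peak was the deposited signal column, taken as a ratio of signal over the authors' background from the column layout of the format, and it was used only to describe, rank or filter peaks within its own list. The deposited p- and q-values of each peak were on a −log10 scale, as the authors' lists gave them. The authors scored peaks by the irreproducible discovery rate (IDR), which estimates how often a peak of that rank would fail to recur between a pair of inputs. Tested on the ranked lists, the deposited score equalled a log-scaled global IDR of its row, within 1 unit, in 100% of rows. The lowest score in every thresholded list was 540, the scaled value of an IDR of 0.05. Ranked lists also held the −log10 p-value of the matched peak in each of the 2 inputs, per the column layout of the deposited format. The deposit names its lists IDR-thresholded, IDR-ranked, pseudoreplicated or replicated. Pseudoreplicates are, in usual practice, random splits of the reads of 1 library or pool, and how these were made was not given in the sources used here. Lists were also derived from a further source whose content was not stated.

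Which inputs a pooled ranked list compared was tested on the files. In 1 of the 2 pooled ranked lists, 75.1% of the input peak starts were found in the replicates' own ranked lists, and 99.9% were found among peaks in the strongest quartile. In the other list the share was 0.0014%. The first was therefore used as the comparison of the 2 replicates and the second as the comparison of pseudoreplicates. All rows of the pooled thresholded list were found in the pseudoreplicate comparison, and all rows of the conservative thresholded list in the replicate comparison. Neither input column was assigned to replicate 1 or replicate 2. No column of per-sample values was left without a place in the design.

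Rows on chromosomes 1 to 19, X and Y whose intervals overlapped by 1 bp or more were merged to regions, each with the summit and enrichment of its strongest row. The main lists were each replicate's own IDR-thresholded list and the pooled IDR-thresholded list. Gene models were from GENCODE mouse release 21 of the M series, and sequence was from the GRCm38 reference, the same assembly as mm10. Of the peaks on these chromosomes, 0 ran past a chromosome end. Of the protein-coding genes, 21884 were used, and 54 that shared a symbol with another gene were left out.

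A region was promoter-overlapping when it came within 1 kb of any annotated transcription start site (TSS) and distal otherwise. For the share by annotation, summits were put in classes in the order promoter, 5′ UTR, 3′ UTR, coding exon, noncoding exon and intron, with the remainder intergenic. A gene had a promoter region when a region came within 1 kb of a TSS of any of its transcripts, and such a region could also overlap the TSS of a neighbour. A distal region was assigned to the gene with the nearest protein-coding TSS within 100 kb of the summit. Nearest position does not show which gene a region acts on.

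Replicate overlap was the share of regions that overlapped a region of the other replicate by 1 bp or more, beside 100 within-chromosome shuffles of the other list. Gene lists were compared with 10000 random lists of the same size, drawn with replacement from other genes and matched on decile of promoter CpG observed over expected (1 kb around the 5′ end) for promoters, or on decile of territory length for distal regions. The territory is the sequence nearer to the gene's TSS than to another, within 100 kb. A list's percentile is its place among the random lists, with ties counted at their middle, and a list under 2.5 or above 97.5 was called below or above the matched range. With 19 lists, 0.95 would fall outside that range by chance. No p-value was computed across genes or peaks, which are not replicates.

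The 19 gene lists were midbrain patterning, ventral midbrain and dopaminergic, other midbrain neurons, neural progenitor, postmitotic neuron, forebrain patterning, hindbrain (mostly Hox), trunk Hox, late glia, neural crest, endothelial, mesenchyme and pericyte, microglia and myeloid, erythroid, cardiac, liver, skeletal muscle, pluripotency and housekeeping. The 12 families taken by symbol were Sox, Pax, Fox, LIM homeobox, POU, Hox, Zic with Irx and Meis, olfactory receptors, vomeronasal receptors, keratins, ribosomal proteins and zinc finger proteins named Zfp. Sox10 and Phox2b each stood in 2 lists.

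Motifs were 25 consensus sequences searched on both strands in windows of 201 bp centred on distal summits. The background was windows of the same size 1 kb to either side of the summit and outside every region of the pooled pseudoreplicated list. Ratios of shares carry intervals from 1000 bootstraps over peaks. A ratio was given only with at least 10 background matches, a minimum set after the first values were seen, because smaller counts gave unbounded intervals.

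Genes and regions named in the text followed a rule fixed before the data were examined, as were the lists, motifs and tests. Exceptions are stated where they occur. From each list the rule took the 2 members with the most distal regions, the 2 with the highest pooled promoter enrichment, and members without a promoter region where 5 or fewer. Ties were named together. It also took the 20 protein-coding genes with the most distal regions, the 10 strongest promoter and 10 strongest distal regions present in both replicates' lists, and En1, Otx2, Pax2, Lmx1b, Wnt1, Fgf8, Foxa2, Foxg1, Hoxb1, Hoxa2, Alb and Myod1.

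Copies of a region were sought with BLAST 2.17.0 in the mitochondrial genome (match of 50 bp or more, E-value limit 1e-05) and in the nuclear genome (megablast, 90% identity or more over 50% of the region). Patches and alternate-strain scaffolds of the reference, which repeat sequence of the chromosomes, were not counted as other places. This exclusion was made after the first values were seen. It lowered the number of random distal regions with another place and left the counts for the strongest promoter and distal regions as they were. The search over regions of the 20 genes with the most distal regions was also added after their values were seen. Sequence was read with samtools 1.23.1. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The list, overlap, motif and shuffle steps were tested on simulated data. With 21884 genes, 1 of 40 random lists left the promoter range, and 40 of 40 lists with all promoters closed were found below it. Closing all promoters is the most extreme change, and no smaller change or raised promoter share was simulated. How often the promoter comparison misses such changes is therefore unknown, and a promoter list inside its range is not shown to be like other genes. For the median distal count, 0 of 40 random lists left the range, and 24 of 40 lists raised 3-fold were found above it. The median therefore misses many raised lists, and a list inside its range is not shown to be like other genes. On the mean distal count, an alternative, 3 of 40 random lists left the range and 39 of 40 raised lists were found.

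The lists held no read counts, so the sequencing depth of each replicate is unknown and no interval here includes it. Exact binomial 95% intervals (Clopper-Pearson) and bootstrap intervals cover counting error over regions, windows or genes only. Alternatives covered other deposited lists, a stricter IDR of 0.01, each replicate's own list in place of the pooled list, other windows and overlap definitions, unmatched random lists and dinucleotide-preserving shuffles for motifs.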

Results

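Chromatin accessibility was measured by ATAC-seq in the midbrain of mouse embryos at embryonic day 11.5, an age at which the midbrain holds dividing progenitors and newly formed neurons. The single group had 2 biological replicates, each a pool of embryos. The deposited values were peak lists without read counts, so the depth of each replicate is unknown. All intervals are 95% intervals for counting error only, and enrichment is the authors' own value for each peak, compared only within a list.

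The first question was how many accessible regions each replicate gave. Replicate 1 had 24976 regions, with a median width of 1027 bp and covering 25.7 Mb, and replicate 2 had 18957 regions, with a median width of 992 bp and covering 18.97 Mb. Replicate 1 thus had 1.32 times as many. The pooled list had 30702 regions covering 31.2 Mb, or 1.15% of the genome, with a median enrichment of 6.37 and a maximum of 53.9. On the autosomes the density was 12.1 regions per Mb, from 9.26 on chromosome 14 to 15.6 on chromosome 11. It was 4.99 per Mb on chromosome X and 0.185 on chromosome Y, which had 17 regions. Counting each deposited summit, or using the pseudoreplicated lists, raised both counts more than 1.5 times, to 67322 or 57951 in replicate 1 and to 49816 or 43611 in replicate 2. Of the pooled summits, 1771 (2.14%) had a deposited q-value of their own above 0.05.

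The replicates were then compared region by region. Of the regions of replicate 2, 18034 of 18957 (95.1%, 94.8 to 95.4) overlapped a region of replicate 1. In the other direction, 17919 of 24976 (71.7%, 71.2 to 72.3) did. Shuffled lists gave at most 2.17% and 1.67%. Promoter regions recurred more often than distal regions. In replicate 1, 86.6% (86.0 to 87.1) of promoter regions and 52.1% (51.2 to 53.1) of distal regions were found in replicate 2, and in replicate 2 the shares found in replicate 1 were 98.4% and 88.7%. Recurrence rose with enrichment, from 33.7% (31.9 to 35.6) in the weakest decile of replicate 1 to 99.96% in the strongest. Regions of replicate 1 found in both lists had a median enrichment of 8.69, against 5.32 for the others, of which 72.9% were distal.

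**Figure D1:**
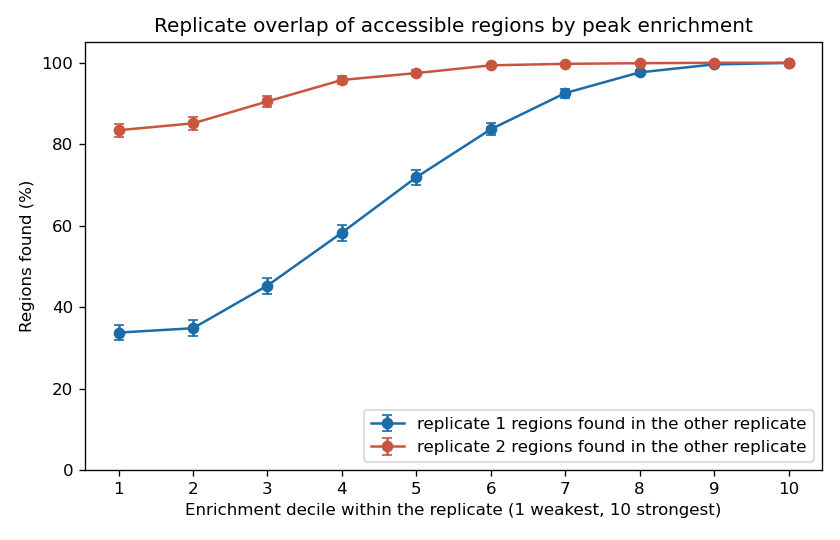
Share of each replicate's regions (%) found in the other replicate, by decile of peak enrichment within the replicate, with exact 95% intervals. Replicate 1 runs from 33.7% to 99.96% and replicate 2 from 83.4% to 100%.

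Across 142215 matched peaks the −log10 p-values in the 2 replicates had a Spearman rho of 0.723 (0.720 to 0.726) and a Pearson r of 0.810 on the log2 scale. Distal peaks alone gave a rho of 0.590 over 84801 peaks. These correlations are across peaks of 1 tissue, and neighbouring summits are not independent. Against the most inclusive list of the other replicate, 817 regions (3.27%, 3.05 to 3.50) were seen in replicate 1 alone and 24 (0.127%, 0.081 to 0.188) in replicate 2 alone. Those of replicate 1 were distal in 85.2% of cases, against 41.6% of its other regions, with a median enrichment of 4.89 against 7.45. Against the thresholded list of the other replicate the counts were 7057 and 923.

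Accessible regions were concentrated at gene starts. In the pooled list 14883 summits (48.5%, 47.9 to 49.0) lay within 1 kb of a transcription start site, a class that takes up 6.05% of the genome, which is 8.01 times the genomic share. Introns held 23.9% of summits against 38.3% of the genome, and intergenic sequence 24.9% against 52.4%. Coding exons held 0.876%, 3′ UTRs 0.954%, noncoding exons 0.863% and 5′ UTRs outside the promoter window 0.078%. Promoter-overlapping regions, 15462 in all, had a median enrichment of 8.52 and a median width of 1204 bp, against 5.31 and 788 bp for the 15240 distal regions. The promoter share was 29.2% in the replicated list, which is longer, and 55.2% and 64.8% in the lists of replicate 1 and replicate 2 alone.

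Promoters of neural progenitor and postmitotic neuron genes were nearly all accessible. Of 21884 protein-coding genes, 13414 (61.3%) had a promoter region in the pooled list. All 20 of the neural progenitor genes did, against a median of 80% in random lists matched on promoter CpG (99.8th percentile), among them Gli3, a transcriptional effector of Hedgehog signalling (enrichment 9.89), and Fabp7, a fatty acid binding protein of radial glia (9.69). Of the postmitotic neuron genes 17 of 18 did (94.4%, random median 61.1%, 100th percentile), led by the synaptic vesicle calcium sensor Syt1 (15.5) and the microtubule-associated protein Map2 (12.7), and only Nhlh2 did not. All 16 housekeeping genes had one (99.4th percentile), with Rplp0 (13.8) and Eef1a1 (13.4) highest. These 3 of the 19 lists lay above their matched range. A region at any start of a gene counted, but CpG was matched only at the gene's 5′ end and the number of starts was not matched. Some members were thus matched to CpG-poor genes, such as Rbfox3 (observed over expected 0.104) and Ywhaz (0.127). How far this lowered the random medians was not tested.

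Hox promoters were mostly without a region. In the hindbrain list, whose Hox genes set segment identity behind the midbrain, 4 of 14 genes had one (28.6%, random median 78.6%, percentile 0), namely Hoxa1, Egr2 (6.06), Mafb (9.18) and Gbx2. In the trunk Hox list 4 of 16 did (25%, random median 93.8%, percentile 0), namely Hoxd10 (7.65), Hoxc10 (4.71), Hoxd9 (4.16) and Hoxd13 (3.73). Over all 39 Hox genes it was 8 (20.5%, random median 84.6%, percentile 0). These genes lie in 4 clusters, while random lists were drawn gene by gene, so the matched range takes no account of neighbouring promoters. The hindbrain, trunk and all-Hox results draw on the same clusters and are not independent. In replicate 1 and replicate 2 alone the shares were 21.4% and 14.3% for the hindbrain list, 12.5% and 6.25% for trunk Hox and 12.8% and 5.13% for all Hox genes, each at percentile 0. Hoxb1 and Hoxa2 had no region in either replicate, and Hoxa1, Hoxd9 and Hoxd13 had a promoter region in the pooled list alone. Pluripotency genes, with Klf4 (7.40) and Tfcp2l1 (6.68) highest, had a region at 3 of 10 (percentile 0.30), and skeletal muscle genes, with Mylpf (8.28) and Myf6 (5.71) highest, at 2 of 10 (percentile 1.62). These 4 lists lay below their range, and 0.95 of 19 would fall outside it by chance. The muscle call ended in the list of either replicate alone (percentiles 3.03 and 6.88), in the conservative list (10.95), in the replicated list (35.9), at the stricter threshold (2.98) and without genes that share a start region (2.70). The pluripotency call ended in the replicated list (9.67) and without CpG matching (2.69).

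The remaining promoter lists lay within range in the pooled list. Midbrain patterning genes had a region at 12 of 16 (75%, percentile 6.08), with the paired box gene Pax5 (13.6) and the engrailed homeobox gene En2 (8.15) highest and Pax7, Wnt1, Fgf8 and Fgf17 without one. Ventral midbrain and dopaminergic genes had 11 of 14, with Nr4a2 (9.99) and the vesicular monoamine transporter Slc18a2 (7.54) highest and Shh, Th and Slc6a3 without one. The list of replicate 1 had no promoter region at Slc18a2. Other midbrain neuron genes had 15 of 18, with Isl1 (12.5) and Nkx6-1 (12.4) highest and Gad1, Sox14 and Phox2b without one. Forebrain patterning genes had 13 of 19 (68.4%, percentile 7.81), with Arx (9.25) and Dlx1 (8.61) highest. This list fell below its range in replicate 1 alone (47.4%, percentile 0.065), in replicate 2 alone (31.6%, percentile 0), in the conservative list (percentile 0.65) and at the stricter threshold (0.32). Without CpG matching the percentiles were 86.7 for midbrain patterning, 90.4 for ventral, 97.4 for other midbrain neuron and 72.5 for forebrain genes, all within range.

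Among lists of other cell types, neural crest genes had a promoter region at 7 of 10, with Mpz (13.5) and Ets1 (12.9) highest and Foxd3, Sox10 and Phox2b without one. Mesenchyme and pericyte genes had 8 of 12, with Foxc1 (8.17) and Foxd1 (6.99) highest and Rgs5, Foxc2, Col3a1 and Lum without one, and fell from 66.7% to 33.3% (percentile 2.78) in replicate 2 alone. Late glia genes had 6 of 14, with Olig1 (8.62) and Olig2 (8.24) highest. Cardiac genes had 4 of 13 (Tbx20, 10.2, and Myh7, 4.86, with a share of 15.4% in replicate 2 alone against 30.8%). Liver genes had 3 of 14 (Foxa3, 10.8, and Apoa1, 7.52), or 21.4%, against 28.6% and 14.3% in replicate 1 and replicate 2 alone. The list of replicate 2 had no promoter region at Olig1, Myh7 or Apoa1. Erythroid genes had 5 of 13, with Klf1 (7.40) and Epor (5.70, absent in replicate 2) highest, at the 95.2nd percentile. Endothelial genes had 5 of 13, with Erg (10.98) and Kdr (7.24) highest, at percentile 3.17, and fell below the range in 6 alternatives, among them replicate 1 alone (1.2), replicate 2 alone (0.745, with a share of 23.1% against 38.5%) and the conservative list (0.64). Microglia and myeloid genes had 0 of 11, at percentile 3.54. With ties counted at their middle, this was the lowest percentile the matched comparison could give. The list could therefore not be called below its matched range. Without CpG matching, the microglia and myeloid (0), cardiac (1.68) and liver (0.14) lists fell below the range, and liver also with a 250 bp window (2.11). The erythroid list rose above it without genes that share a start region (98.2), and stood at 14.4 at the stricter threshold and 5.36 without CpG matching. Its share fell from 38.5% to 23.1% in replicate 1 alone (percentile 68.3) and 7.69% in replicate 2 alone (22.2).

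**Figure D2:**
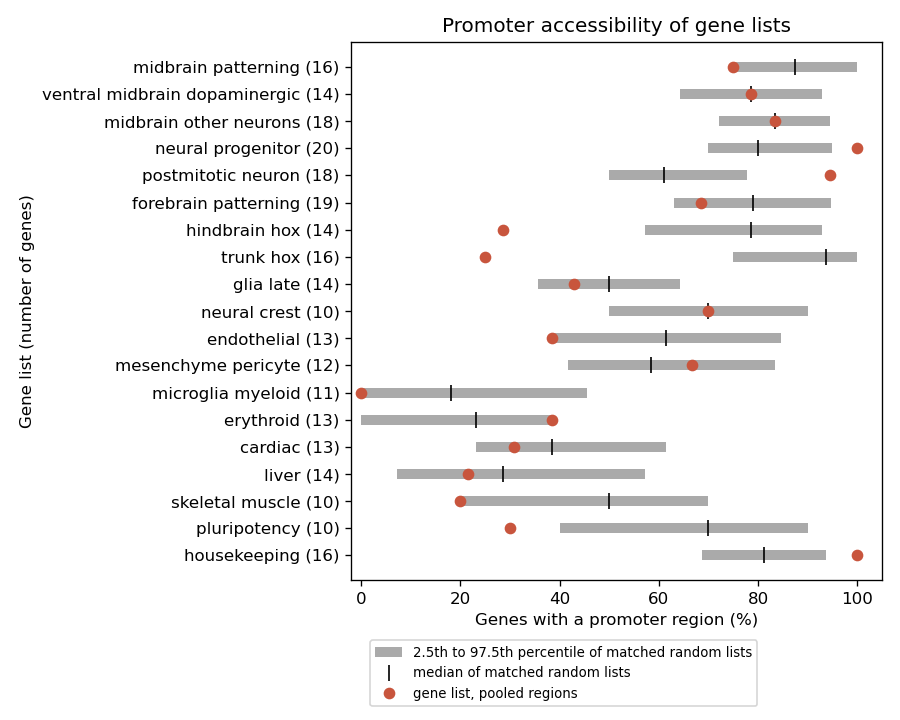
Share of genes with a promoter region (%) for the 19 gene lists (points), with the central 95% (bars) and the median (ticks) of random lists matched on promoter CpG. Neural progenitor and housekeeping lists stand at 100% and trunk Hox at 25%.

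Distal regions were most numerous near midbrain patterning and neural progenitor genes. Midbrain patterning genes had a median of 3.5 distal regions per gene (100th percentile among lists matched on territory length, random median 0), with at least 1 at 14 of 16 genes. Otx1 had 11 and Otx2, a homeobox gene needed for forebrain and midbrain identity, had 9. Neural progenitor genes had a median of 3 (100th percentile), led by Cdh2 (8), Sox1 (7) and Sox9 (7). Ventral midbrain and dopaminergic genes had 2.5 (100th percentile), led by Foxa2 (8) and then by Ddc, Foxa1 and Msx1 (4 each). Postmitotic neuron genes had 2 (99.97th percentile), led by Rbfox3 (7) and Nhlh2 (4), and other midbrain neuron genes had 1.5 (99.9th percentile), led by Ascl1 (7), Tal2 (4) and Tfap2b (4). Late glia genes had 1 (98.7th percentile), led by Aldh1l1 (5), Mbp (4) and Slc1a3 (4).

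By percentile, these 6 of 19 lists lay above their range. The late glia median of 1 equalled the upper end of its matched range, also 1, so that call rested on counting ties at their middle. On the mean, late glia genes stood at percentile 99.6. Postmitotic neuron genes did not in the conservative list (percentile 95.2) or with all regions within 50 kb (94.1), and other midbrain neuron genes did not in the conservative list (95.5). On the mean, postmitotic neuron genes stood at percentile 98.24, and within range in replicate 2 alone (83.28, against 98.625 in replicate 1 alone). With 2 replicates, the medians from replicate 1 and replicate 2 alone were 3 and 1.5 for midbrain patterning, 2.5 and 2 for progenitors, 1.5 and 1 for ventral genes, 1.5 and 0.5 for postmitotic neurons and 1 and 0.5 for late glia. Counts at single genes also fell, to 7 and 7 for Otx1, 5 and 4 for Otx2 and 6 and 4 for Sox1. They fell to 7 and 4 for Foxa2, 3 and 2 for Ddc and 3 and 1 for Foxa1 and Msx1. They fell to 3 and 2 for Nhlh2, 1 and 1 for Tfap2b, 4 and 1 for Aldh1l1 and 3 and 2 for Mbp. Tal2 kept its 4 in replicate 1 alone but had 2 in replicate 2 alone. Rbfox3 had 3 and 1, so its lead rested on the pooled list.

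Forebrain patterning genes had a median of 1 distal region at the 95.7th percentile, with Dlx2 (6) and Nkx2-1 (3) leading. The percentile was 99.1 in replicate 1 alone, 49.96 in replicate 2 alone and 49.35 at the stricter threshold. Neural crest genes also had a median of 1 (88.1), with Ets1 and Ednrb at 5 each, as did mesenchyme and pericyte genes (90.3), with Foxc1 at 3. Without matching on territory both lay above the range (98.3 and 98.8). Neural crest genes stood at 46.8 in replicate 2 alone, and mesenchyme and pericyte genes at 41.2 and 48.4 in replicate 1 and replicate 2 alone. The other lists had a median of 0. In the trunk Hox list 0 of 16 genes had a distal region assigned and in the hindbrain list 4 of 14 did, with Gbx2 at 3. The trunk Hox list was not below its range, at percentile 50 on the median and 20.1 on the mean. Its genes can have short territories, such as Hoxd10 with 7702 bp, which had 2 distal regions within 50 kb. At least 1 distal region lay near 6 of 13 endothelial genes (Cdh5, 4), 4 of 11 microglia and myeloid genes (Ptprc, 4, then Spi1 and C1qb, 2 each), 5 of 13 cardiac genes (Hand2, 2), 4 of 14 liver genes (Ttr, 2) and 1 of 13 erythroid genes (Gypa, 1). It was 2 of 10 for skeletal muscle (Myf5 and Des, 1 each), 3 of 10 for pluripotency (Klf4, 3, and Esrrb, 2) and 4 of 16 for housekeeping genes (Ywhaz, 3, then Ubc and Eef1a1, 2 each). In replicate 1 and replicate 2 alone the counts of genes were 2 and 1 for the hindbrain list, 3 and 1 for microglia and myeloid, 5 and 2 for cardiac, 1 and 2 for liver, 0 and 0 for erythroid, 2 and 1 for skeletal muscle and 3 and 2 for pluripotency genes. Replicate 2 alone had 0 distal regions at Gbx2, Nkx2-1, Foxc1, Ptprc, Spi1, Des and Esrrb, 1 at Eef1a1 and 3 at Ednrb. Dlx2 had 4 and 2, Cdh5 2 and 2, and Klf4 1 and 1, and Ttr and Gypa had 0 in either replicate alone. The test on simulated lists raised 3-fold found 24 of 40, so a list within its range is not shown to lack an excess.

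**Figure D3:**
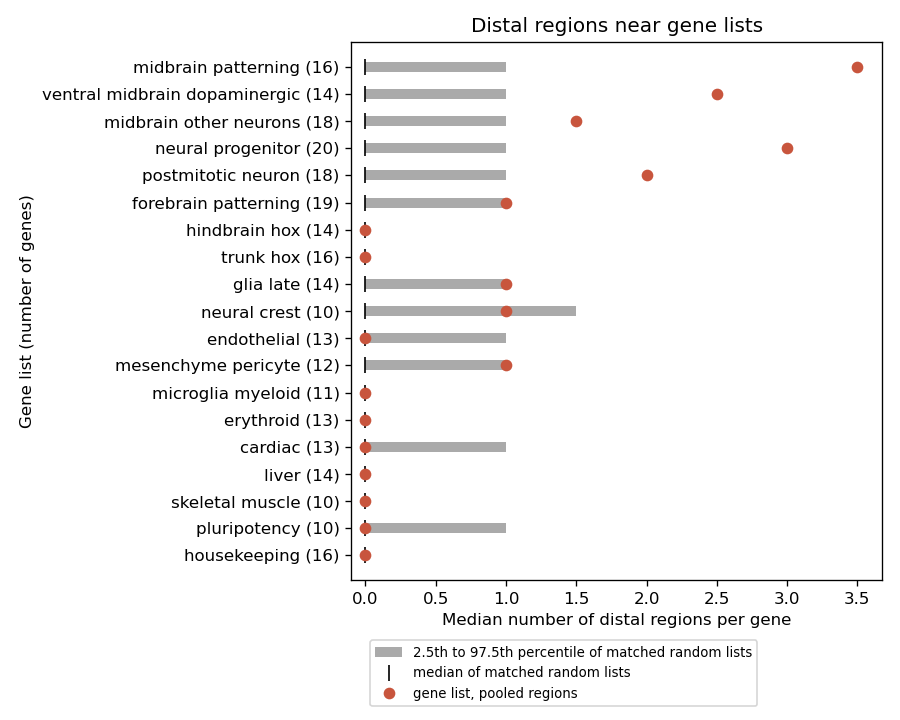
Median number of distal regions per gene for the 19 gene lists (points), with the central 95% (bars) and the median (ticks) of random lists matched on territory length. Midbrain patterning stands at 3.5 and neural progenitors at 3, and most lists of other tissues stand at 0.

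At single loci of the mm10 assembly, Otx2 (chromosome 14, 48657677 to 48673819, minus strand) had a promoter region of enrichment 4.03 that replicate 2 lacked. Its strongest distal regions, at 48709404 to 48710302 (7.78) and 48737327 to 48738657 (7.28), lay in introns of the antisense gene Otx2os1 and were in both replicates. En1, an engrailed homeobox gene of the midbrain-hindbrain boundary, had a promoter region of 5.25 and 2 distal regions (1 in replicate 2 alone), the stronger at chromosome 1, 120643906 to 120645065 (8.34), in an intron of 2610027F03Rik. Wnt1, a signalling gene of the same boundary, had no promoter region but an intergenic region 8303 bp away at chromosome 15, 98797581 to 98798705 (11.9), in both replicates. Fgf8, the signal secreted at that boundary, had none at its promoter and 2 distal regions, at chromosome 19, 45717432 to 45718387 (intergenic, 6.60, both replicates) and 45736863 to 45737876 (Fgf8 intron, 3.91, neither replicate alone).

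Lmx1b, a LIM homeobox gene of dopaminergic progenitors, had 3 distal regions in its own introns and 2 promoter-overlapping regions. The stronger (4.53, both replicates) had its summit in an intron, 1546 bp from the nearest protein-coding TSS. The other (3.67), with its summit 577 bp from one, was in the pooled list alone. Foxa2, a forkhead factor of the floor plate, had a promoter region of 4.23 and 8 distal regions, the strongest at chromosome 2, 148114449 to 148115179 (intergenic, 9.48, replicate 1 alone). Pax2 had a promoter region of 4.02 and 1 distal region in the pooled list alone. Foxg1, a forebrain regulator, had a promoter region of 8.60 and 0 distal regions assigned to it, though 2 lay within 50 kb of its 5′ end. Alb and Myod1, genes of liver and muscle, had no region, and 0 distal regions lay within 50 kb of either.

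**Figure D4:**
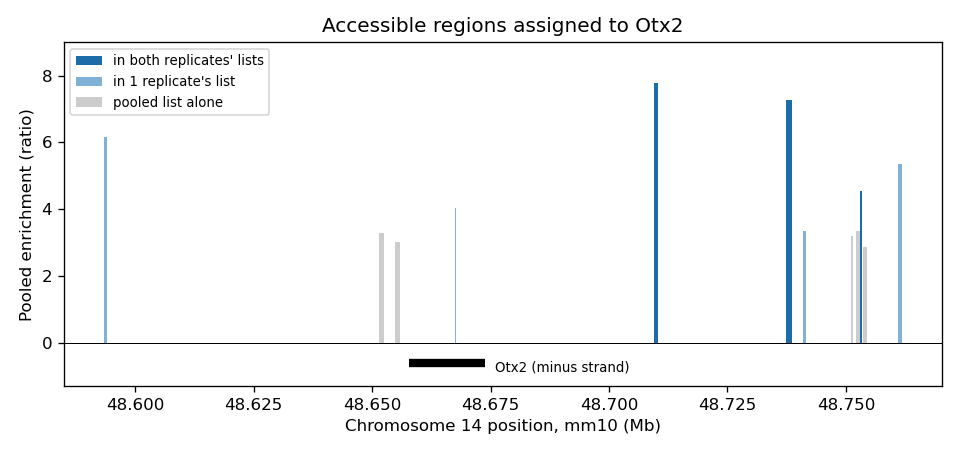
Map of the pooled regions assigned to Otx2 on chromosome 14 (mm10, Mb), with bar height giving pooled enrichment (ratio) and colour the replicates whose list holds the region. The strongest, at 7.78 and 7.28, were in both replicates.

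Over all protein-coding genes, 5981 (27.3%) had at least 1 distal region, and 4824 and 3237 did in replicate 1 and replicate 2 alone. The 20 with most were Gse1 (19), the axon guidance receptor gene Robo1 (18), the neurexin gene Nrxn3 (16), Bach2, Frmd4a, Tenm3 and Usp29 (14 each), Casz1, Celf4, Maml3, Nav2, Sdk2 and Tiam1 (13 each), Pde4d and Sh3rf1 (12 each), and Auts2, Cdk14, Otx1, Sertad2 and Sfi1 (11 each). Of the 11 regions of Sfi1, 9 had another place in the nuclear genome, against 0 for each of the other 19 genes. In replicate 2 alone these 20 genes had 3 to 9 each. These counts were not matched on territory length. All 20 genes lay in decile 9 or 10 of territory length, from 161920 bp for Sfi1 to 1565398 bp for Pde4d, so long territories alone could place genes here.

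The strongest distal regions present in both replicates were mostly intergenic. The first 3 were intergenic, at chromosome X, 143482935 to 143483180 (enrichment 53.9), chromosome 2, 69355469 to 69355735 (53.0) and chromosome 2, 3964419 to 3964690 (41.4). The others were at chromosome 10, 96077546 to 96077951 (38.6), chromosome 5, 60042692 to 60043142 (37.4), chromosome 12, 97061367 to 97061856 (29.1), chromosome 16, 17222199 to 17222580 (27.1), chromosome X, 76598498 to 76599194 (25.8, Cldn34d intron), chromosome 6, 9889877 to 9890225 (25.1) and chromosome 17, 17004588 to 17005430 (24.8). Of these 10, 5 matched mitochondrial DNA over 50 bp or more, against 0 of 200 random distal regions (upper bound 1.83%), and 4 had another place in the nuclear genome, against 2 of 200 (0.121 to 3.57%). The 2 groups overlapped, and 6 of the 10 had either kind of match, against 2 of 200.

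The strongest promoter regions included those of the zinc finger gene Zfp960 (chromosome 17, 17063543 to 17064344, 24.1), Wdr17 (chromosome 8, 54724011 to 54725063, 22.6) and the threonyl-tRNA synthetase gene Tars (chromosome 15, 11399274 to 11400157, 22.5). The others lay at starts of Gm11407, Gm11408 and Gm11410 (27.6), Gm10060 (26.9), Gm10583, Gm13274 and Gm13286 (25.8), 6720489N17Rik and Gm24020 (23.8), Gm22256 and Gm49359 (23.5), 2610005L07Rik (22.9) and Gm24270 within Peak1 (22.6). Of these 10, 8 had another place in the nuclear genome and 1, the strongest, at Gm11407, matched mitochondrial DNA over 361 bp. Whether reads were shared between such places was not tested.

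Sequence motifs were counted in 15099 windows at distal summits and 27279 flanking windows. The consensus of CTCF, an insulator protein, was in 6.83% of summit windows and 0.0990% of flanks (ratio 69.1, 50.1 to 111). Without replicate 1 it was in 4.32% of windows, with a ratio of 34.7 (22.4 to 73.1). That of ASCL proneural factors was in 23.7% against 8.34% (2.84, 2.70 to 2.99) and that of SOX factors in 15.3% against 6.93% (2.20, 2.09 to 2.33). Ratios also lay above 1 for SP and KLF (6.24, 5.22 to 7.55), ETS (3.03, 2.02 to 4.48, but 4.91 without replicate 1 and 4.59 in narrower windows), ZIC (2.84, 2.66 to 3.02), POU (2.62, 2.28 to 3.01), OTX and PITX (1.35, 1.27 to 1.44), NFY (1.32, 1.24 to 1.41) and NEUROG (1.14, 1.1004 to 1.18). They lay below 1 for the homeobox core (0.788, 0.724 to 0.854), RUNX (0.736, 0.665 to 0.808) and GATA (0.576, 0.5003 to 0.657). Of 25 motifs, 19 had a ratio, and 6 of these (LEF and TCF, FOX, TEAD, AP1, HNF4 and MEF2) had an interval that included 1. The other 6 had too few flank matches for a ratio. RFX was in 175 windows and 4 flanks, NRF1 in 17 and 6, REST in 13 and 2, NFI in 7 and 2, YY1 in 5 and 2, and HNF1 in 0 of either.

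Summit windows held more G and C than flanks (52.7% against 43.9%). Against dinucleotide-preserving shuffles of the same windows, the homeobox core turned to 3.28 (2.84 to 3.78), RUNX to 1.27 (1.13 to 1.45) and NFY to 0.841, GATA no longer differed from 1 (0.862, 0.718 to 1.01), and FOX went from 0.959 to 2.41, LEF and TCF from 0.952 to 1.15 and TEAD from 1.04 to 1.54 (1.21 to 2.02). ASCL fell to 1.51 and ZIC to 1.42, while POU rose to 4.39, OTX and PITX to 2.05, and CTCF was 54.4. Against flanks in narrower windows, AP1 was 1.23 (1.06 to 1.41) and LEF and TCF 0.870 (0.786 to 0.956). FOX was 0.816 (0.675 to 0.978) without replicate 1, and LEF and TCF 0.921 (0.844 to 0.9997) without replicate 2.

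**Figure D5:**
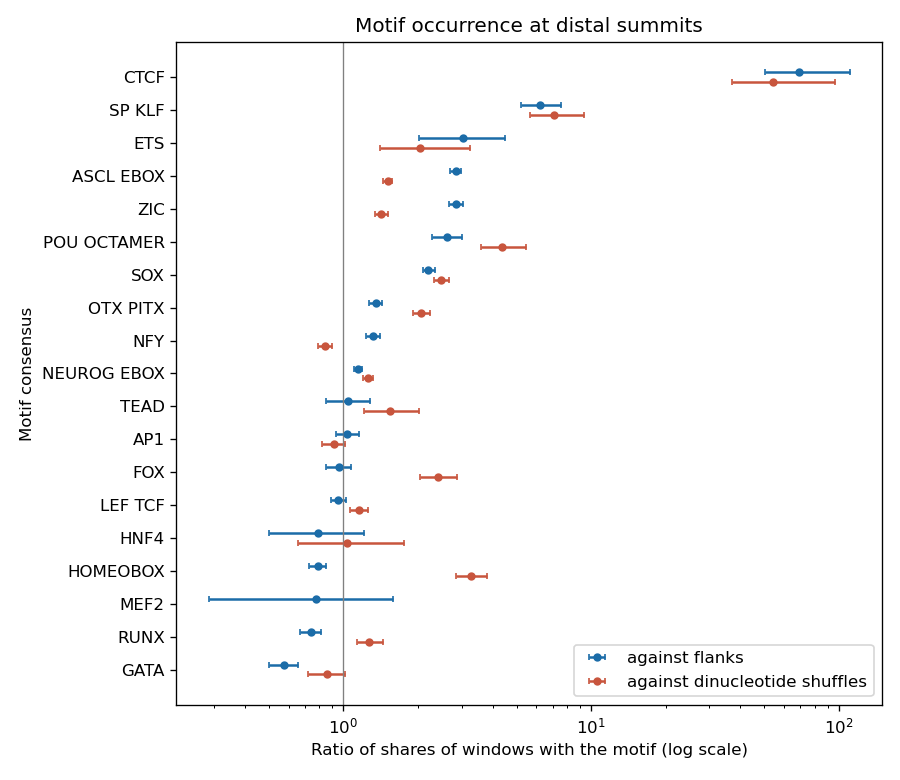
Ratio of the share of distal summit windows with a motif to the share in flanks or in dinucleotide shuffles (log axis), with 95% bootstrap intervals. CTCF stands at 69.1 against flanks, and the homeobox core stands at 0.788 against flanks and 3.28 against shuffles.

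The pooled list was last compared with the conservative list deposited for the same libraries. Of the pooled regions 4493 (14.6%, 14.24 to 15.03) were missing from the conservative list. They had a median enrichment of 4.13 and were distal in 80.5% of cases, against 44.3% of the others. In the other direction 2285 conservative regions (8.02%, 7.71 to 8.34) were missing from the pooled list, of which 81.3% were distal.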

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

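The tests weighed here were written down before their results were seen, with 4 exceptions added after values were seen. These were the distal-only comparison of the 2 pools with the requirement that both ratios hold, the exclusion of patch and alternate-strain scaffolds from the search for other nuclear places, the base rate for midbrain genes, which changed how that test was read, and the test of promoter CpG at Hox genes.

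Signal also appeared in the ranked lists outside the regions analysed. Past the IDR threshold, 163 pooled peaks, 94 of replicate 1 and 79 of replicate 2 lay outside the assembled chromosomes, 0 of them on mitochondrial DNA. A further 207, 188 and 163 peaks on the chromosomes passed the threshold but were absent from the thresholded lists, with median enrichments of 3.46, 3.77 and 4.51.

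The strongest distal regions stood apart in sequence. Regulatory regions of midbrain genes stay open, since 0 of 10 had as nearest gene a member of a midbrain or progenitor list, but only 276 of 15240 distal regions (1.81%) did, so 83.3% of random draws of 10 would have none and the bound set beforehand was too weak to exclude them. Nuclear copies of mitochondrial DNA are a candidate explanation for part of them, since 5 of 10 matched, exactly the number set beforehand as the minimum, against 0 of 200 random distal regions. Sequence present several times in the genome stays open, with 4 of 10, between the bounds set beforehand, against 2 of 200 random distal regions. These 2 explanations covered overlapping regions, since 6 of 10 had either kind of match. The 5 regions that did not match mitochondrial DNA are not covered by the first of them. No biological explanation by group was tested because there was 1 group.

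Replicate 2 had fewer regions than replicate 1. Weak regions missed in replicate 2 may account for this. The share of replicate 1 regions found there rose with enrichment, from 33.7% in the weakest decile to 99.96% in the strongest. This met the bound set beforehand. That strongest decile was only 6.77% distal, and a different cell mixture could give the same rise. In the most inclusive list of replicate 2, 89.8% of the weakest decile was found, and 817 of all 24976 regions (3.27%) were not. Most regions missing from the thresholded list of replicate 2 thus had a peak there that did not pass the threshold. Why these peaks were weaker is not shown, since a different cell mixture could also weaken them and depth is unknown. A different cell mixture in the 2 pools stays open. Regions of replicate 1 alone lay near non-neural marker genes 2.27 times (1.31 to 3.88) as often as shared regions, which met the bound set beforehand, but among distal regions the ratio was 1.32 (0.654 to 2.73), from 17 of 5148 against 14 of 5609. No biological difference between the pools was tested.

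Few Hox promoters had a region. A strict threshold of the list is argued against as the whole cause. In the most inclusive pooled list 46.2% of Hox promoters had one, still at percentile 0 beside a random median of 89.7%. That share was above the 20.5% of the main pooled list, so the threshold may account for part of the shortfall. CpG content of the Hox promoters is argued against as the whole cause, since their share of 20.5% stood at percentile 0 beside lists matched on CpG, and the 50 genes nearest in CpG to each had a mean share of 84.2%. Peaks not callable in these CpG-rich clusters stay open only as a lower yield, since the pooled list had 1, 1, 2 and 6 regions in HoxA, HoxB, HoxC and HoxD, while 1 of the 4 clusters had a region in both replicates and 2 in either. No comparison tissue was analysed here, so no biological explanation was tested.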

How the results depend on the processing

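Among the alternatives, 1 peak per region, the mean in place of the median and the use of summits with a q-value of 0.05 or less were chosen after seeing the data. Of 787 values under alternatives, 655 stayed on their side of the threshold, within their interval or within 1.5 times, 10 changed direction with the main value, the alternative or both called, and 122 weakened, strengthened or moved. The 655 include 51 list percentiles that crossed 50 within the matched range and 4 motif ratios that crossed 1 with intervals that included it, so their direction was not kept. Unless the setting itself shows it, the cause was not tested. The unknown depth limits all counts of regions, and 2 replicates of 1 group allowed no test between groups. No paired analysis was possible because there was 1 group.

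Replicates 1 and 2 had 57951 and 43611 regions in the pseudoreplicated lists, and 67322 and 49816 when each summit was counted. The share of replicate 1 found in replicate 2 and its reverse were 69.5% and 91.5% with reciprocal overlap of 50%, 70.4% and 93.2% with summits within 100 bp, 65.9% and 89.5% in the pseudoreplicated lists, and 83.3% and 84.0% in lists of equal length. The second was 97.1% at the stricter threshold. The correlation was 0.758 past the IDR threshold, 0.590 for distal peaks and 0.820 with 1 peak per region. The promoter share was 40.6% with a 250 bp window, 50.4% by region overlap, 50.8% in the conservative list, 29.2% in the replicated list and 55.2% to 64.8% with 1 replicate left out. Regions seen in 1 replicate numbered 7057 and 923 against the thresholded list of the other, which is shorter by construction.

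The number of gene lists with promoters below the matched range was 2 in the replicated list. The forebrain promoter percentile was 0.65 in the conservative list, 0.32 at the stricter threshold and 0 to 0.065 with 1 replicate left out. Its distal percentile was 97.54 in the conservative list, 99.97 in the replicated list, 99.2 without territory matching, 97.9 on the mean and 49.96 to 99.1 with 1 replicate left out. Without CpG matching, the promoter percentiles of the Sox and Fox families turned to 86.1 and 62.0. The distal percentile of the Fox family was 49.75 in the conservative list, 49.98 at the stricter threshold and 49.97 to 50 with 1 replicate left out, where its median tied with that of most random lists. Against dinucleotide shuffles, 1 motif lay below, and ratios turned for the homeobox core (3.28), FOX (2.41), RUNX (1.27), LEF and TCF (1.15) and NFY (0.841).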

Other observations

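Every test in this part was among those set before the data were examined, apart from the comparison on means.

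Gene families taken by symbol differed in promoter accessibility. Zinc finger genes named Zfp had a promoter region at 308 of 365 (84.4%, random median 72.3%, 100th percentile) and ribosomal protein genes at 73 of 76 (99.7th percentile, 60.6 without genes that share a start region and 94.1 in the replicated list). LIM homeobox genes had 11 of 12 (98.7), but 68.7 and 82.1 in replicate 1 and replicate 2 alone. Fox genes had 28 of 44 (63.6%, percentile 0, 28.4 in the replicated list) and Sox genes 14 of 19 (percentile 1.57, 3.34 and 13.7 in the 2 replicates alone). Without CpG matching neither family fell below its range. Pax genes had 7 of 9, POU genes 10 of 15 and Zic, Irx and Meis genes 13 of 14, all within range. Olfactory receptors had 4 of 1091, vomeronasal receptors 2 of 325 and keratins 3 of 106, each at percentile 0. In replicate 2 alone these shares fell from 0.367% to 0.183%, 0.615% to 0.308% and 2.83% to 0.943%, still at percentile 0. For all these families, as for the Hox genes, random lists were drawn gene by gene and take no account of neighbouring genes. Whether sequence copies affected the calls at family members was not tested.

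In distal regions, POU genes had a median of 2 per gene (99.8), or 1 in either replicate alone (94.98 in replicate 1), and Fox genes 1 (99.7, about 50 in either replicate alone). Zic, Irx and Meis genes had 1.5 (96.4, above the range in replicate 2 alone at 99.1). Sox genes had 1 (88.7, 99.8 in replicate 2 alone), LIM homeobox genes 1 (88.9), or 0.5 in replicate 2 alone, and Pax genes 1 (73.6). At least 1 distal region lay near 3 of 39 Hox genes, 31 of 1091 olfactory receptors, 14 of 325 vomeronasal receptors, 10 of 106 keratins, 18 of 76 ribosomal protein genes and 84 of 365 Zfp genes, all with a median of 0. In replicate 1 and replicate 2 alone these counts were 0 and 0, 25 and 16, 9 and 7, 9 and 5, 15 and 9, and 67 and 53, in the same order. On the mean, the Fox (100), Sox (99.98), POU (99.4) and ribosomal protein (97.6) families lay above the range and the olfactory and vomeronasal receptors below it, at percentile 0. The ribosomal proteins were within it in either replicate alone (97.1 and 82.3), while Pax genes, at 96.4, lay above it in both (98.3 and 99.7), and Zic, Irx and Meis genes, at 96.96, in replicate 2 alone (97.7). Over all Hox genes it was 25.5, and 2.28 in replicate 1 alone.

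The 4 Hox clusters differed in their regions. HoxD had 6 pooled regions, 3 in replicate 1 and 1 in replicate 2, and HoxC had 2, 2 and 0. HoxA and HoxB had 1 each in the pooled list and 0 in either replicate. Besides the genes of the fixed lists, Hoxc13, Hoxc5 and Hoxd1, named after their values were seen, had a promoter region.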
